A study of Danio rerio with 12 samples.

How the data were processed

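Total RNA from adult zebrafish hearts, extracted with Trizol and labelled with biotin, was hybridised to 12 Affymetrix Zebrafish Genome Arrays, with 3 arrays each for unamputated and amputated WT (AB line) and dnHIF1a hearts. The deposited values are log2 expression per probe set after RMA (background correction, quantile normalization and median-polish summary), made by the authors, and they were used as deposited. The submitters' processing notes name RMA and limma without versions and do not say which step used which. No filter or fold cutoff is stated there, so none was applied. The labels number the arrays of each group from 1 to 3 without naming pairs. The correlations of within-group deviations between arrays sharing a number ran from -0.191 to 0.133, so the number was not used as a block except as an alternative. The number of arrays limits the precision, and the highest share of identical values between any 2 arrays was 2.87%.

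Of 15617 probe sets, 115 controls were left out and 15502 were tested. The platform table gives 10795 of these a single gene, 135 several genes and 4572 none. Symbols were matched through Entrez identifiers to the zebrafish RefSeq table for 10711 probe sets, with 84 unmatched and 1 symbol updated. For statements on genes, the probe set with the highest mean over all arrays stands for its gene, which gave 8793 genes, 1539 of them with more than 1 probe set. Probe positions on the genome were not analysed here.

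A limma model with a mean per group was fitted to all 12 arrays in R 4.3.3 with limma 3.58.1 (default empirical Bayes prior, 8 residual and 4.46 prior degrees of freedom). Its moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets in each of 5 comparisons. A probe set was called at an adjusted p under 0.05. The comparisons were amputated against unamputated hearts in WT and in dnHIF1a, the difference of these responses (dnHIF1a minus WT), and dnHIF1a against WT in unamputated and in amputated hearts. The groups, these comparisons, the tests, the gene lists, the rule for named genes and all alternatives except the erythrocyte covariate were chosen before the data were examined.

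Gene lists were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, and p-values were adjusted over the 30 lists. The 16 lists of processes were DNA replication, mitosis, extracellular matrix, matrix enzymes and collagen processing, HIF targets outside glycolysis, glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, ribosomal proteins, ER chaperones and secretory load, heat shock response, immediate-early genes, interferon response, p53 response and apoptosis, and heart regeneration signals. The 14 marker lists were cardiomyocyte, epicardium and fibroblast, endothelium and endocardium, macrophage and pan-leukocyte, neutrophil, lymphocyte, erythrocyte, thrombocyte, smooth muscle and bulbus, skeletal muscle, liver, epithelium, exocrine pancreas and gut, and gonad. The ribosomal list is drawn by symbol prefix and also takes in rps6ka kinase genes. Some genes sit in more than 1 list, among them 3 of 30 matrix genes, 5 of 20 epicardium and fibroblast markers and 1 of 24 erythrocyte markers. A further 4 lists (clock repressor and D-box genes, clock genes with ROR elements, glucocorticoid and FOXO targets, class I antigen processing) were chosen after the data were seen and given no list test.

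Named genes are, for each comparison, up to 8 higher and up to 8 lower genes with the largest difference among those called whose groups do not overlap, leaving out clone-style symbols. They further include up to 2 members per direction of each list with the smallest p, and, in the amputation comparisons and their difference, hif1aa, hif1ab, epas1a, epas1b, egln3, vegfaa, vegfab, myl7, pcna, nppa, gata4, aldh1a2, tbx18, fn1a, col1a2 and postnb where measured. The procedure was tested on simulated data with 200 changed probe sets of 15502 in the same design. At 1.5-fold, 2-fold and 3-fold it recovered 77.6%, 92.5% and 95.5% of them in the WT response (9 false calls), 71.6%, 95.5% and 97.0% in the dnHIF1a response (6) and 49.2%, 86.6% and 90.9% in the difference of the responses (7). It recovered 77.6%, 97% and 97.0% between unamputated genotypes (10) and 79.1%, 95.5% and 97.0% between amputated genotypes (13). In the same test camera called the 1 shifted list and 0 of the others. The simulated noise was independent between genes, so this does not show how often camera calls lists of correlated genes falsely.

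The alternatives were a repeated quantile normalization, median centring of each array, leaving out the dimmest or the flattest part of the probe sets, a trended and robust prior, array weights, a fold cutoff, only the groups compared, the replicate number as a block, and leaving out each array in turn. For lists and genes they also included the highest-variance probe set, the mean of all probe sets and a gene's other probe sets. The mean of the erythrocyte list per array as a covariate was added after the data were seen.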

Results

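Expression was measured on 12 Affymetrix Zebrafish Genome Arrays hybridised with RNA from adult zebrafish hearts, with 3 arrays in each of 4 groups. Wild-type (WT) hearts came from the AB line. The dnHIF1a hearts came from a transgenic line whose name gives a dominant negative form of HIF1a, the oxygen-regulated transcription factor subunit. The name places it under the heart muscle promoter cmlc2a (myl7), together with a Cre recombinase of the tamoxifen-dependent type. Hearts came from unamputated fish or were taken 7 days after amputation. The series asks whether hypoxia signalling has a role in the regrowth of heart muscle. Each array gave a value for 15617 probe sets, of which 15502 were tested, and array medians lay between 5.54 and 5.58 on the log2 scale. The values carry no measure of background, so differences are those of the measured values, and no size is given where a group compared lies under 4, a line set after the data were seen. The first principal component held 36.4% of the variance, the second 29.6% and the third 8.77%. Pearson correlations across probe sets were 0.992 to 0.996 between arrays of one group and 0.976 to 0.99 between arrays of different groups. The labels do not say whether the arrays of a group come from separate animals or pools, so the p-values measure the spread between these samples. They do not give the background of the transgenic line or say whether tamoxifen was given, and a genotype difference here is a difference between these lines. Values in the text are differences of group means in log2 units ± the standard error from limma, with 3 arrays per group and limma p-values adjusted by the Benjamini-Hochberg method.

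The array carries a probe set for hif1ab and none that measured hif1aa, vegfab or nppa. The hif1ab probe set read between 9.37 and 10.34 on the 12 arrays, which checks nothing about the transgene, since the probe set need not share its sequence. Amputation was not followed by a called change of hif1ab, with -0.27 ± 0.18, adjusted p = 0.302 in WT and 0.057 ± 0.18, adjusted p = 0.899 in dnHIF1a. The related subunit genes epas1a (0.21 ± 0.087, adjusted p = 0.108) and epas1b (-0.13 ± 0.11, adjusted p = 0.421) did not pass the test in WT, nor did they in dnHIF1a (-0.027 ± 0.087, adjusted p = 0.903 and -0.22 ± 0.11, adjusted p = 0.238). Of the genes named as similar to hif1a, chosen after the data were seen, hif1al2 rose in WT (2.06 ± 0.36, adjusted p = 0.00161). With the mean of the erythrocyte list as a covariate that call was lost (0.79 ± 0.39, adjusted p = 0.284). In dnHIF1a hif1al2 did not pass the test (0.37 ± 0.36, adjusted p = 0.616), and the difference of the responses did not either (-1.69 ± 0.51, adjusted p = 0.108), but was called without WT amputated array 2 (adjusted p = 0.019). For hif1al neither response passed the test (0.36 ± 0.14, adjusted p = 0.0875 in WT and -0.36 ± 0.14, adjusted p = 0.153 in dnHIF1a), nor did their difference (-0.72 ± 0.20, adjusted p = 0.0897). Without WT unamputated array 3 the WT response (adjusted p = 0.0432) and the difference (0.0432) of hif1al were called, and the difference also without dnHIF1a unamputated array 3 (0.0448).

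The comparison of amputated with unamputated WT hearts asks how the heart transcriptome differs 7 days after amputation. Genes of the extracellular matrix were among those that rose most. The matrix protein gene postnb (periostin) rose 21.4-fold (4.42 ± 0.23, adjusted p = 1.11e-07) and fn1a (fibronectin) 15.9-fold (3.99 ± 0.26, adjusted p = 6.77e-07). The type I collagen gene col1a2 rose 7.08-fold (2.82 ± 0.14, adjusted p = 9.89e-08). The growth factor gene mdka (midkine) rose 11.8-fold, the iron carrier gene tfa (transferrin) 14.6-fold and the chaperone gene clu (clusterin) 8.07-fold. The muscle receptor kinase gene musk (3.38 ± 0.44, adjusted p = 0.000244) and the circadian repressor gene ciarta (4.08 ± 0.14, adjusted p = 1.33e-08) rose from unamputated levels of 4.34 ± 0.75 and 4.64 ± 0.20 (SD, n = 3), under the array median. The steepest fall was that of nfil3-5, a transcription factor of the circadian network (-3.66 ± 0.31, adjusted p = 7.13e-06). It was followed by cisha (-2.18 ± 0.26), trim55a (-2.03 ± 0.14), rrad (-1.84 ± 0.19), rnasekb (-1.66 ± 0.38), cry4 (-1.35 ± 0.10), tp53bp1 (-1.28 ± 0.18) and cd82a (-1.28 ± 0.16). With the mean of the erythrocyte list as a covariate the calls of rnasekb (-0.96, adjusted p = 0.404), tp53bp1 (-0.95, adjusted p = 0.0889) and cd82a (-0.82, adjusted p = 0.0511) were lost. The replication gene pcna (0.093 ± 0.25, adjusted p = 0.819) did not pass the test, nor did the cardiac muscle gene myl7 (-0.083 ± 0.061, adjusted p = 0.349). The latter read 14.58 to 14.80 on the 12 arrays, near the array maxima of 14.86 to 15.04, so its values do not show that it was stable. Nor did aldh1a2 (0.49 ± 0.21), egln3 (-0.54 ± 0.22), vegfaa (-0.06 ± 0.19), gata4 (-0.14 ± 0.079) and tbx18 (0.17 ± 0.097), with adjusted p between 0.0983 and 0.847. Of the 2 other probe sets of fn1a in the same comparison, the first was called higher (adjusted p = 0.00874) and the second fell (-0.21, adjusted p = 0.0457). The first read 3.85 to 3.94 on unamputated WT arrays, so no size is given. A second probe set each of postnb and col1a2 read 3.89 and 3.43, that of tp53bp1 -0.59 (adjusted p = 0.0189) and that of rnasekb, not called, -1.16 (adjusted p = 0.0574).

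Of the 30 measured genes of the extracellular matrix list, 23 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.90 and an adjusted p of 8.37e-19 in limma's camera test. Among them col1a1a read 2.42 and col5a2a 2.14. The list of matrix enzymes and collagen processing had 10 members higher and 1 lower of 17 (11 and 1 adjusted over the list alone; median 1.03, adjusted p = 1.09e-07). The protease genes mmp2 (2.45 ± 0.11, adjusted p = 4.39e-08) and mmp14a (2.24 ± 0.092, adjusted p = 4.39e-08) rose and plod3 (-0.34) fell. Of 20 epicardium and fibroblast markers 12 rose and 0 fell (15 and 1 adjusted over the list alone; median 0.76, adjusted p = 2.94e-10). Macrophage and pan-leukocyte markers rose too, 17 of 25 higher and 0 lower (19 and 0 adjusted over the list alone; median 0.53, adjusted p = 4.64e-10). Among them were apoeb (2.72 ± 0.33, adjusted p = 0.00015) and grna (0.79 ± 0.094, adjusted p = 0.000126). Epithelial markers had 11 higher and 1 lower of 33 (11 and 1 adjusted over the list alone; median 0.24, adjusted p = 0.000134). The keratin gene krt15 (2.58) and anxa1a (1.93) led them. With an estimated correlation between genes the calls of the extracellular matrix (adjusted p = 0.00445) and the epicardium and fibroblast list (adjusted p = 0.00763) held. The others did not, with adjusted p = 0.192 with an estimated correlation for matrix enzymes, 0.205 for macrophages and 0.278 for epithelium. With the mean of the erythrocyte list as a covariate the median was 0.31 for macrophages and 0.027 for epithelium, both still called. Without WT amputated array 3 that of epithelium was 0.043.

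Red blood cell genes were higher in the same arrays: 15 of 24 erythrocyte markers rose and 2 fell (16 and 2 adjusted over the list alone; median 0.79, adjusted p = 9.2e-06; adjusted p = 0.475 with an estimated correlation). Their mean level was 8.81 ± 0.42 (SD, n = 3) in amputated and 7.83 ± 0.17 in unamputated WT hearts. Members that rose include epb41b (1.99 ± 0.37, adjusted p = 0.00236) and nt5c2l1 (2.33 ± 0.39, adjusted p = 0.00121), while the haem synthesis genes cpox (-0.45) and alad (-0.35) fell. Mitochondrial respiration genes fell, 29 of 87 members of the oxidative phosphorylation list lower and 3 higher (40 and 3 adjusted over the list alone; median -0.18, adjusted p = 3.83e-06; adjusted p = 0.475 with an estimated correlation). Examples are ndufa5 (-0.58) and ndufa2 (-0.46), against a rise of cox4i2 (0.90). With the mean of the erythrocyte list as a covariate the oxidative phosphorylation call was lost (median -0.14, adjusted p = 0.0554). That of the erythrocyte list itself was lost by construction, since its own mean is the covariate (-0.064, adjusted p = 0.824). Among 25 HIF targets outside glycolysis 9 rose and 2 fell (9 and 4 adjusted over the list alone; median 0.023, mean 0.47, adjusted p = 0.0364; adjusted p = 0.205 with an estimated correlation). This call was lost without WT unamputated array 2 (median -0.0033, adjusted p = 0.126). With the erythrocyte covariate the median was 0.32, and without single arrays it moved by over 1.5 times to 0.12 (WT unamputated 1), -0.0033 (WT unamputated 2), 0.17 (WT unamputated 3), 0.073 (WT amputated 1), 0.055 (WT amputated 2) and 0.06 (WT amputated 3). Members were led by tfa (3.87) and bhlhe41 (2.08), with slc16a3b (-1.26) and insig2 (-0.23) lower. The gene bhlhe41 is also among the clock repressor and D-box genes, for which an effect of amputation cannot be told apart from collection at another phase of the day. Of 54 heart regeneration signals 11 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.048, adjusted p = 0.0447; adjusted p = 0.192 with an estimated correlation). That call was lost without WT unamputated array 2 (adjusted p = 0.0566) or 3 (0.0717), WT amputated array 2 (0.101) or dnHIF1a unamputated array 3 (0.0571). Its median moved by over 1.5 times without single arrays, to 0.023 (WT unamputated 1), 0.026 (WT unamputated 2), 0.023 (WT unamputated 3) and 0.0025 (WT amputated 2). Among its members mdka and jag1b (0.60) rose and her6 (-0.88) fell.

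Immediate-early genes (9 higher and 2 lower of 38, 10 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.0146) included atf3 (1.41) and klf2b (-0.85). The p53 and apoptosis list (6 higher and 0 lower of 16, 6 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.0151) included caspa (0.79). Smooth muscle and bulbus markers (2 higher and 1 lower of 8, 5 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.0447) included tagln (2.55). Skeletal muscle markers also shifted up as a list (median 0.23, adjusted p = 0.0146) with 0 of 28 members called, and 0 adjusted over the list alone. With an estimated correlation these 4 list calls were not made. It gave adjusted p = 0.475 with an estimated correlation for immediate-early genes, 0.278 for p53, 0.368 for smooth muscle and 0.529 for skeletal muscle. The erythrocyte covariate also ended the calls of p53 (median 0.061, adjusted p = 0.158) and smooth muscle (0.11, adjusted p = 0.259), and the skeletal muscle median turned to -0.082 (adjusted p = 0.803). Without WT unamputated array 2 the calls of immediate-early genes (adjusted p = 0.105) and p53 (0.0531) were lost, and without WT amputated array 3 that of skeletal muscle (0.127). Without single arrays the median moved by over 1.5 times, for immediate-early genes to 0.032 (WT unamputated 2) and 0.33 (WT unamputated 3) and for skeletal muscle to 0.10 (WT amputated 3), and with the covariate it was 0.42 for immediate-early genes. The smooth muscle call was lost without WT unamputated array 2 (0.0609), WT unamputated array 3 (0.0773) or WT amputated array 3 (0.0879). The other lists did not pass the test in WT. Their medians were -0.11 for glycolysis, -0.11 for tricarboxylic acid cycle, 0.043 for fatty acid oxidation, 0.0033 for ribosomal proteins, -0.077 for ER chaperones and secretory load, -0.22 for heat shock response, -0.17 for interferon response, -0.093 for cardiomyocyte and -0.027 for endothelium and endocardium, with adjusted p between 0.0831 and 0.83 over all such lists. The remaining medians were 0.35 for neutrophil, -0.043 for lymphocyte, 0.19 for thrombocyte, -0.028 for liver, -0.12 for exocrine pancreas and gut, -0.13 for gonad, 0.09 for DNA replication and 0.098 for mitosis. Members called in these lists include the cardiac myosin gene myh7 (1.98 ± 0.30, adjusted p = 0.00058), the heat shock factor gene hsf2 (1.68 ± 0.17, adjusted p = 4.09e-05) and cs (-0.70), the gene of citrate synthase.

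In all, 3532 of 15502 probe sets (22.8%) were called in WT, 1702 higher and 1830 lower, and 374 of them differed by at least 1 log2 unit, 330 higher and 44 lower. With the mean of the erythrocyte list as a covariate 654 were called, 460 higher and 194 lower. In WT that mean was 7.654 to 7.999 on unamputated and 8.325 to 9.067 on amputated arrays. Since these ranges do not overlap, the covariate also takes up change due to amputation. The lower count does not show how much of the response follows blood.

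The comparison of amputated with unamputated dnHIF1a hearts asks the same of the transgenic line. The matrix gene fn1a rose 8.04-fold (3.01 ± 0.26, adjusted p = 2.2e-05) and clu 6.12-fold (2.61 ± 0.27, adjusted p = 7.52e-05). The repressor gene ciarta rose by 2.83 ± 0.14, adjusted p = 1.19e-06. Also higher were mdka (2.43 ± 0.21), tfa (2.33 ± 0.17), fosl2 (1.99 ± 0.31), tagln (1.98 ± 0.22) and lipg (1.97 ± 0.22). Of these, fosl2 encodes an AP-1 factor, tagln a smooth muscle protein and lipg a lipase. The matrix genes postnb (1.82 ± 0.23, adjusted p = 0.000391) and col1a2 (1.46 ± 0.14, adjusted p = 5.97e-05) rose as well, as did aldh1a2, the gene of a retinoic acid synthesis enzyme (0.99 ± 0.21, adjusted p = 0.0104). The steepest fall was again that of nfil3-5 (-3.88 ± 0.31, adjusted p = 1.49e-05). It was followed by lrrc4.1 (-1.76 ± 0.16), sox11b (given below), rcan3 (-1.69 ± 0.23), ypel3 (-1.59 ± 0.18), rorcb (-1.56 ± 0.18), stc2a (-1.48 ± 0.14) and trim55a (-1.37 ± 0.14). The growth factor gene vegfaa read 0.66 ± 0.19, adjusted p = 0.0476, a call lost without any of 8 arrays (dnHIF1a unamputated 1, 2 and 3, WT unamputated 1, dnHIF1a amputated 1 and 2, WT amputated 1 and 3), with an adjusted p of up to 0.172. The call of sox11b (-1.70 ± 0.40, adjusted p = 0.0187) was lost without dnHIF1a unamputated array 1 (adjusted p = 0.0771) or 2 (0.0788) or dnHIF1a amputated array 1 (0.051) or 2 (0.0721). Of its other probe sets the first was called (-1.80) and the second was not (-0.37, adjusted p = 0.133). Values for myl7, near the top of the scale (-0.063 ± 0.061, adjusted p = 0.608), and pcna (0.14 ± 0.25, adjusted p = 0.811) did not pass the test, nor did those for egln3 (0.15 ± 0.22), gata4 (-0.11 ± 0.079) and tbx18 (0.23 ± 0.097). Of the 2 other probe sets of fn1a, the first was not called (adjusted p = 0.153) and the second read -0.13 (adjusted p = 0.326). The first read 3.82 to 3.85 on unamputated dnHIF1a arrays, so no size is given.

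Leukocyte markers had the highest median of the 30 lists. Of 25 macrophage and pan-leukocyte markers 19 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.92, adjusted p = 1.63e-22). Among them were grna (1.65 ± 0.094, adjusted p = 2.79e-06) and the myeloid factor gene spi1b (1.43 ± 0.13, adjusted p = 3.72e-05). Of 30 extracellular matrix genes 16 rose and 0 fell (17 and 1 adjusted over the list alone; median 0.46, adjusted p = 1e-14). Examples are lamb1a (1.32) and col5a2a (1.12). Matrix enzymes had 13 higher and 0 lower of 17 (14 and 0 adjusted over the list alone; median 0.81, adjusted p = 1.58e-11), including mmp14a (1.27) and mmp14b (1.06). Epicardium and fibroblast markers had 11 higher and 0 lower of 20 (13 and 0 adjusted over the list alone; median 0.54, adjusted p = 1.26e-10), including fn1b (1.81). Heart regeneration signals had 8 higher and 1 lower of 54 (9 and 2 adjusted over the list alone; median 0.072, adjusted p = 0.0108), including the chemokine gene cxcl12a (0.86). These 5 calls held with an estimated correlation, with adjusted p of 0.00746 for matrix, 0.00746 for epicardium and fibroblast, 0.0442 for matrix enzymes, 0.0442 for macrophages and 0.0442 for regeneration signals.

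Neutrophil markers (2 of 9 higher, 0 lower, 2 and 0 adjusted over the list alone, median 0.31, adjusted p = 0.0108) were also called, with mmp9 (1.31) among them. So was the heat shock response (3 higher and 1 lower of 22, 6 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.0183), with hsp90aa1.1 (1.67). Glycolysis genes (4 higher and 0 lower of 29, 6 and 0 adjusted over the list alone, median 0.063, adjusted p = 0.0266) included aldocb (0.83) and ldhbb (0.96). Skeletal muscle markers (1 higher and 0 lower of 28, 1 and 0 adjusted over the list alone, median 0.20, adjusted p = 0.0161) included acta1a (1.43). These calls were not made with an estimated correlation: adjusted p = 0.0642 with an estimated correlation for neutrophils, 0.685 for heat shock, 0.385 for glycolysis and 0.699 for skeletal muscle. Erythrocyte markers did not pass the test (median 0.072, adjusted p = 0.578, 0 of 24 higher and 1 lower). Nor did HIF targets outside glycolysis (median 0.087, adjusted p = 0.177, 5 higher and 2 lower of 25) or oxidative phosphorylation (median -0.06, adjusted p = 0.323). The call of glycolysis was lost without dnHIF1a amputated array 2 (adjusted p = 0.0613), and that of skeletal muscle without dnHIF1a amputated array 3 (0.453). That of heat shock was lost without dnHIF1a unamputated array 2 (0.0715) or dnHIF1a amputated array 2 (0.116). Without single arrays the median moved by over 1.5 times for neutrophils, to 0.51 (dnHIF1a unamputated 1). It did so for heat shock, to 0.24 (dnHIF1a unamputated 3), 0.19 (dnHIF1a amputated 1) and 0.18 (dnHIF1a amputated 3), and for skeletal muscle, to 0.34 (dnHIF1a amputated 2) and 0.019 (dnHIF1a amputated 3). In all, 1511 probe sets (9.75%) were called, 877 higher and 634 lower, and of the 164 that differed by at least 1 log2 unit 140 higher and 24 lower. The count fell to 909 without dnHIF1a amputated array 1, 929 without array 3 of that group, and 964 and 981 without dnHIF1a unamputated arrays 1 and 2.

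**Figure D1:**
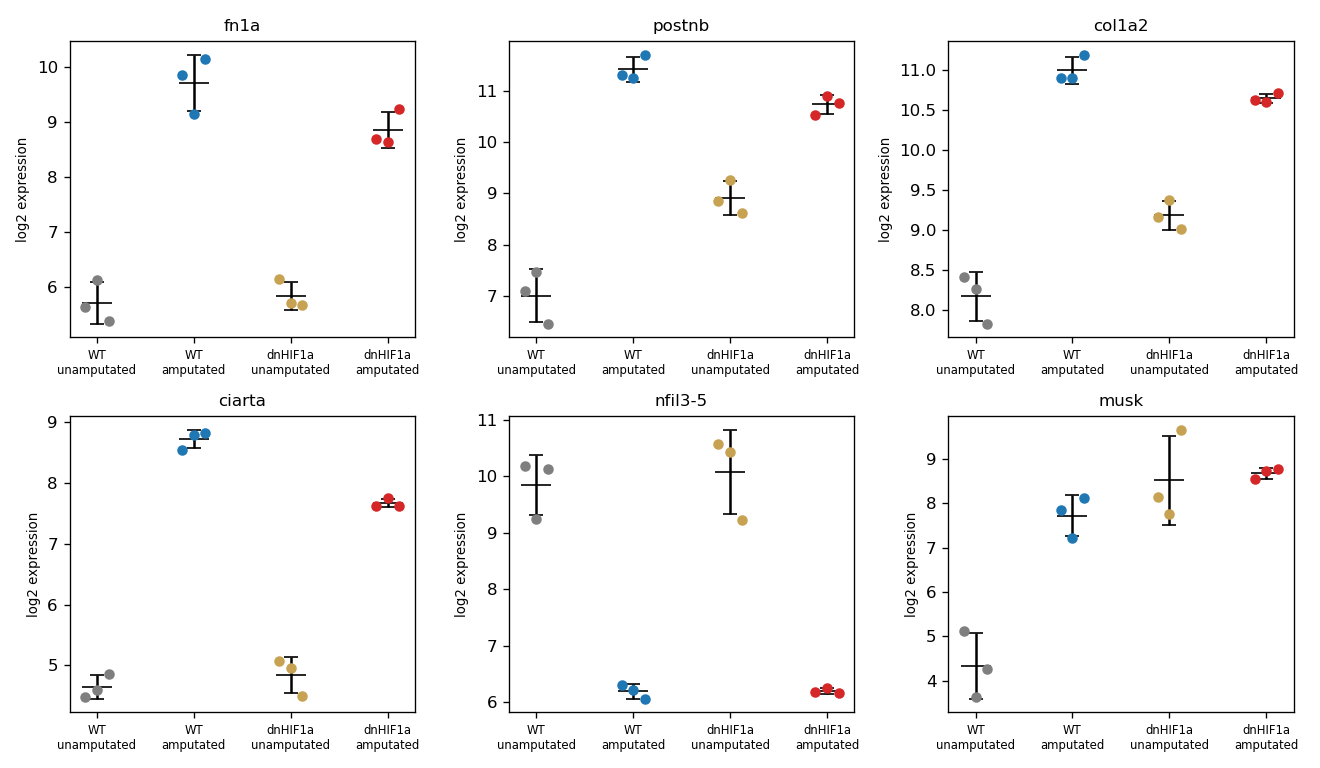
Log2 expression of 6 genes on each array (points), by group, with the group mean and 1 SD (bars, n = 3). fn1a, postnb, col1a2 and ciarta are higher and nfil3-5 is lower in the amputated groups of both genotypes, and musk reads 4.34 ± 0.75 in unamputated WT hearts and 8.52 ± 1.01 in unamputated dnHIF1a hearts.

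The difference of the 2 responses, dnHIF1a minus WT, asks whether the effect of amputation depends on the genotype. Matrix genes rose less in dnHIF1a hearts. The response of postnb was 6.05-fold smaller (-2.60 ± 0.33, adjusted p = 0.00342) and that of col1a2 2.57-fold smaller (-1.36 ± 0.20, adjusted p = 0.00779). The difference for fn1a did not pass the test (-0.99 ± 0.36, adjusted p = 0.179). For postnb the group levels were 7.00 ± 0.51 and 11.42 ± 0.25 (SD, n = 3) in unamputated and amputated WT hearts and 8.91 ± 0.33 and 10.74 ± 0.19 in dnHIF1a hearts. Of 30 extracellular matrix genes 7 had a lower response and 0 a higher one (16 and 0 adjusted over the list alone; median -0.45, adjusted p = 1.92e-09). This call held with an estimated correlation (adjusted p = 0.0428). Other genes whose response was lower in dnHIF1a were ccng2 (-2.26 ± 0.31, adjusted p = 0.0051), a cyclin gene, and arrdc2 (-2.11 ± 0.26, adjusted p = 0.00335). The response was higher for odc1, the gene of ornithine decarboxylase (2.34 ± 0.38, adjusted p = 0.0114), for the immunoproteasome gene psmb8a (1.60 ± 0.25, adjusted p = 0.00985) and for phlda3 (1.28 ± 0.23, adjusted p = 0.0177). These calls, from postnb to phlda3, were kept without any single array. A second probe set gave -2.06 for postnb, -1.63 for col1a2 and -1.90 for ccng2, all called, and a second probe set of arrdc2 gave -0.14 (adjusted p = 0.654).

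The same rule names 10 more genes whose call was lost without at least 1 array. Responses were lower for musk (-3.23 ± 0.62), tppp3 (-1.99 ± 0.42), zdhhc2 (-1.90 ± 0.39), nt5dc2 (-1.80 ± 0.33) and ifi44f1 (-2.05 ± 0.47), and higher for socs3b (2.18 ± 0.48), cisha (1.67 ± 0.37), pprc1 (1.45 ± 0.28), psmb12 (1.35 ± 0.25) and ywhag2 (1.35 ± 0.26). Without single arrays, the adjusted p rose to at most 0.11 for ifi44f1, 0.096 for cisha, 0.0903 for socs3b, 0.0855 for tppp3 and 0.0746 for zdhhc2. For the rest it rose to at most 0.0611 for musk, 0.0571 for pprc1, 0.0561 for ywhag2, 0.054 for nt5dc2 without dnHIF1a amputated array 2 and 0.0509 for psmb12 without dnHIF1a amputated array 1. The arrays in question were dnHIF1a amputated 1 and 2, WT amputated 1 and 3 for musk; dnHIF1a unamputated 1 and 2, WT unamputated 2, dnHIF1a amputated 1 and 2, WT amputated 3 for tppp3; dnHIF1a unamputated 1 and 2, dnHIF1a amputated 1 for zdhhc2. They were dnHIF1a unamputated 1 and 2, WT unamputated 2 and 3, dnHIF1a amputated 1 and 2, WT amputated 1 and 3 for ifi44f1; dnHIF1a unamputated 1 and 2, dnHIF1a amputated 1, 2 and 3, WT amputated 1, 2 and 3 for socs3b; dnHIF1a amputated 1 and 2, WT amputated 1 for pprc1; dnHIF1a unamputated 1 and 2, dnHIF1a amputated 2 for ywhag2, and for cisha the same as for socs3b. No difference of responses passed the test for vegfaa (0.72 ± 0.27), egln3 (0.70 ± 0.32), aldh1a2 (0.50 ± 0.29) and hif1ab (0.33 ± 0.25), nor for epas1a (-0.23 ± 0.12), epas1b (-0.097 ± 0.15), tbx18 (0.057 ± 0.14), pcna (0.05 ± 0.35) and gata4 (0.03 ± 0.11) and, near the top of the scale, myl7 (0.02 ± 0.086).

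Among the other lists, epicardium and fibroblast markers responded less in dnHIF1a (5 lower and 0 higher of 20, 7 and 0 adjusted over the list alone; median -0.23, adjusted p = 0.00115). So did matrix enzymes (3 lower and 0 higher of 17, 6 and 2 adjusted over the list alone; median -0.067, adjusted p = 0.0448), where mmp2 read -1.51. Epithelial markers (3 lower and 0 higher of 33, 5 and 0 adjusted over the list alone; median -0.18, adjusted p = 0.000861) included krt15 (-1.76). Erythrocyte markers had the lowest median (-0.80, adjusted p = 6.85e-06) with 0 lower and 1 higher of 24, or 13 and 1 adjusted over the list alone. Of 24 values 3 lay above 0. Responses were higher in dnHIF1a for macrophage and pan-leukocyte markers (1 higher and 0 lower of 25, 2 and 0 adjusted over the list alone; median 0.32, adjusted p = 0.00226), where grna read 0.86. The mean of that list went from 6.64 to 7.53 in dnHIF1a and from 7.43 to 8.06 in WT hearts. Its larger log2 rise in dnHIF1a thus began from a lower level and ended below that of WT. Heat shock genes (4 of 22 higher, 7 adjusted over the list alone; median 0.42, adjusted p = 0.000108) and glycolysis genes (4 of 29 higher, 4 adjusted over the list alone; median 0.21, adjusted p = 0.00445), where aldocb read 1.01, also had higher responses. Cardiomyocyte markers (3 of 25 higher, 5 adjusted over the list alone; median 0.19, adjusted p = 0.00226) and oxidative phosphorylation (1 of 87 higher and 1 lower, 2 and 1 adjusted over the list alone; median 0.13, adjusted p = 8.38e-06) followed. None of these 9 calls was made with an estimated correlation, which gave adjusted p = 0.229 for epicardium and fibroblast, 0.482 for matrix enzymes, 0.403 for epithelium and 0.481 for erythrocytes. It gave 0.481 for macrophages, 0.403 for heat shock, 0.381 for glycolysis, 0.381 for cardiomyocytes and 0.481 for oxidative phosphorylation. With the erythrocyte covariate 6 of these calls were lost, with adjusted p = 0.135 for matrix enzymes (median -0.0079), 0.0544 for epithelium (-0.072) and, by construction, 0.839 for erythrocytes (-0.025). It was 0.0544 for glycolysis (0.14), 0.0544 for cardiomyocytes (0.15) and 0.0863 for oxidative phosphorylation (0.095). The matrix enzyme call was also lost without dnHIF1a unamputated array 3 (adjusted p = 0.0743), dnHIF1a amputated array 1 (0.0623), WT unamputated array 2 (0.34) and WT amputated arrays 1 (0.0706) and 3 (0.0985). Its median moved by over 1.5 times without single arrays, to -0.34 (WT unamputated 1), -0.01 (WT unamputated 3), -0.027 (dnHIF1a amputated 1), -0.12 (dnHIF1a amputated 2), -0.33 (WT amputated 2) and -0.005 (WT amputated 3). Other medians moved likewise to -0.13 (dnHIF1a unamputated 1), -0.36 (WT unamputated 1), -0.11 (dnHIF1a amputated 3) and -0.14 (WT amputated 3) in epicardium and fibroblast, to 0.12 (WT unamputated 1) and 0.12 (WT amputated 3) in glycolysis and to -0.018 (WT amputated 3) in epithelium. HIF targets outside glycolysis did not pass the test (median -0.11, 0 higher and 4 lower of 25, adjusted p = 0.122), although tfa (-1.54) and stc2a (-1.11) had lower responses.

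In all, 347 probe sets (2.24%) differed in their response, 137 higher and 210 lower in dnHIF1a. Of these, 200 were called in the WT response only, 65 in the dnHIF1a response only and 81 in both. Among them 140 differed between genotypes before amputation and not after, and 139 after and not before. Without single arrays the count fell to 149 and 162 (dnHIF1a amputated 1 and 2), 194 and 161 (dnHIF1a unamputated 1 and 2) and 175 and 228 (WT amputated 1 and 3). It rose to 590 without WT unamputated array 3. With the erythrocyte list mean as a covariate 24 were called, 7 higher and 17 lower. The genes col1a2 (-1.11 ± 0.24, adjusted p = 0.0952), postnb (-2.24 ± 0.40, adjusted p = 0.0554), odc1 (2.67 ± 0.48, adjusted p = 0.0588), ccng2 (-2.35 ± 0.41, adjusted p = 0.0554), arrdc2 (-1.90 ± 0.33, adjusted p = 0.0553) and phlda3 (1.46 ± 0.30, adjusted p = 0.0844) were no longer among them. Neither were musk (-3.01 ± 0.82, adjusted p = 0.167), ifi44f1 (-0.86 ± 0.28, adjusted p = 0.245), tppp3 (-2.08 ± 0.55, adjusted p = 0.159), zdhhc2 (-2.47 ± 0.43, adjusted p = 0.0554) and nt5dc2 (-1.31 ± 0.38, adjusted p = 0.187). The same holds for socs3b (2.31 ± 0.63, adjusted p = 0.17), cisha (1.92 ± 0.48, adjusted p = 0.134), pprc1 (1.54 ± 0.36, adjusted p = 0.115) and ywhag2 (1.42 ± 0.34, adjusted p = 0.12), while psmb8a (2.00 ± 0.27, adjusted p = 0.0207) and psmb12 (1.72 ± 0.28, adjusted p = 0.0397) stayed. Of these 15 lost calls, 14 had a larger error with the covariate, and in 9 the value was at least as large as without it. Across 8793 genes the 2 responses had a Pearson correlation of 0.588 and a Spearman correlation of 0.483, over genes, which are not independent replicates. Of 588 genes called in both genotypes 575 had the same sign, 329 higher and 246 lower in both, where independent lists of those sizes would share 60.0 and 65.5. The response was smaller in dnHIF1a for 385 of them (65.5%). Both responses are tested with the same estimate of spread per gene, so the called lists are not independent and would overlap beyond those numbers. Collection at another phase of the day, if shared by the amputated arrays, would also give calls of the same sign.

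**Figure D2:**
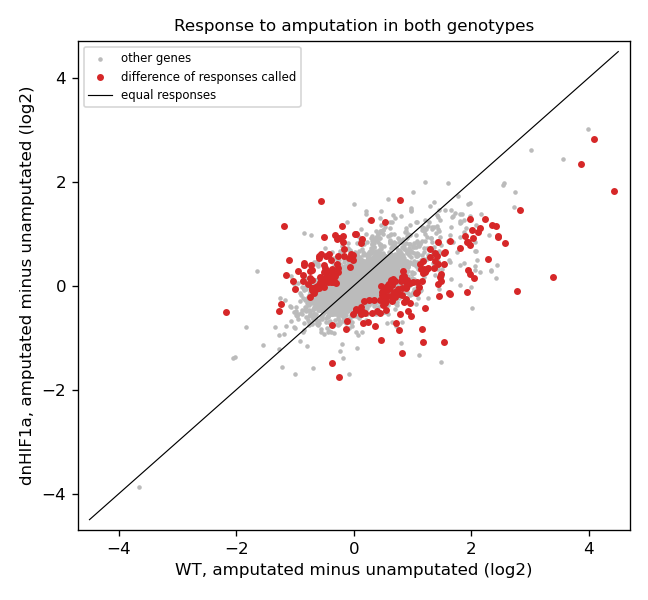
Log2 response to amputation of 8793 genes, WT on the horizontal and dnHIF1a on the vertical axis. Red points are genes whose difference of responses was called, the line marks equal responses, and the correlation is 0.588 over genes.

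The comparison of unamputated dnHIF1a with unamputated WT hearts asks how the lines differ without amputation. The class I histocompatibility gene mhc1ufa was higher in dnHIF1a hearts at 9.75 ± 0.36 (SD, n = 3) against 3.51 ± 0.20 (adjusted p = 1.05e-08), and so was slc25a14 at 6.08 ± 0.63 against 3.03 ± 0.24 (adjusted p = 0.000118). These WT levels are low on the scale of the arrays, and the values do not show whether they stand above background, so no size of the difference is given. The sulfotransferase gene sult2st1 (4.29 ± 0.20, adjusted p = 1.04e-07), musk (4.18 ± 0.44, adjusted p = 6.56e-05), the glycogen phosphorylase gene pygl (3.24 ± 0.19, adjusted p = 5.85e-07) and the cell cycle inhibitor gene cdkn1ca (2.98 ± 0.38, adjusted p = 0.000292) were higher too. So were tppp3 (3.14 ± 0.30) and elmo2 (2.6 ± 0.27), with tppp3 at 4.21 ± 0.52 and musk at 4.34 ± 0.75 in WT, not far above the line of 4. Of the 2 other probe sets of slc25a14, the first was not called (adjusted p = 0.582) and the second was (adjusted p = 1.72e-05). The other probe sets of pygl read 2.4 and 1.05, both called. Lower in dnHIF1a were the immunoproteasome genes psmb8a (-2.0 ± 0.18, adjusted p = 1.73e-05) and psmb12 (-1.76 ± 0.17, adjusted p = 3.97e-05) and the collagenase gene mmp13a (-1.98 ± 0.41, adjusted p = 0.0076). Also lower were the aldolase gene aldocb (-1.75 ± 0.097, adjusted p = 3.21e-07) and rnasekb (-2.46 ± 0.38), ak1 (-2.07 ± 0.11), ass1 (-1.84 ± 0.29) and mpp2b (-1.78 ± 0.13), the last at 4.09 ± 0.09 in dnHIF1a. These are the same 3 WT arrays against which the WT response is measured.

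Leukocyte markers were lower in unamputated dnHIF1a hearts, with 16 of 25 macrophage and pan-leukocyte markers lower and 0 higher (19 and 0 adjusted over the list alone; median -0.86, adjusted p = 6.33e-15). Examples are grna (-1.53 ± 0.094, adjusted p = 6.74e-07) and ptprc (-1.24 ± 0.11, adjusted p = 1.65e-05). The interferon response list had 8 lower and 0 higher of 16 (8 and 1 adjusted over the list alone; median -0.36, adjusted p = 0.000132). It includes psmb13a (-1.74) and psmb9a (-1.44). Of the 11 class I antigen processing genes treated at the end, 6 are also in this list, so the results of these lists are not independent. Heat shock genes had 8 lower and 1 higher of 22 (11 and 3 adjusted over the list alone; median -0.25, adjusted p = 0.0069). Matrix genes were higher, 9 higher and 2 lower of 30 (13 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00127). Among them were postnb (1.91 ± 0.23, adjusted p = 0.000191) and col1a1a (0.97 ± 0.12, adjusted p = 0.000236). Epicardium and fibroblast markers (6 higher and 0 lower of 20, 7 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.00221) included vim (1.04). Smooth muscle and bulbus markers (4 higher and 0 lower of 8, 4 and 1 adjusted over the list alone; median 0.71, adjusted p = 0.0129) included acta2 (1.74). The ribosomal protein list shifted up (median 0.087, adjusted p = 0.000285) with 3 of 79 members higher and 1 lower, or 0 and 0 adjusted over the list alone. None of these calls was made with an estimated correlation. It gave adjusted p = 0.255 with an estimated correlation for macrophages, 0.297 for interferon, 0.635 for heat shock, 0.255 for matrix, 0.255 for epicardium and fibroblast, 0.359 for smooth muscle and 0.879 for ribosomal proteins. In all, 1764 probe sets (11.4%) were called, 902 higher and 862 lower. The heat shock call was lost without WT unamputated array 1 (adjusted p = 0.107).

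The comparison of amputated dnHIF1a with amputated WT hearts asks how the lines differ 7 days after amputation. The genes sult2st1 (3.15 ± 0.20, adjusted p = 1.7e-06) and pygl (3.07 ± 0.19, adjusted p = 1.37e-06) were again higher in dnHIF1a. Against low WT levels, so without a size, mhc1ufa (9.45 ± 0.43 against 3.29 ± 0.28, SD, n = 3, adjusted p = 1.23e-08), slc25a14 (5.62 ± 0.80 against 3.15 ± 0.055, adjusted p = 0.000687) and aacs (5.82 ± 0.16 against 3.80 ± 0.21, adjusted p = 8.37e-07) were higher too. Further genes that were higher are lims2 (2.24 ± 0.11), rgs5a (2.17 ± 0.22) and arpp21 (2.1 ± 0.39). Other probe sets read 2.28 and 0.89 for pygl, 1.36 for rgs5a and 0.44 for arpp21, all called. Of those of slc25a14, the first was not called (adjusted p = 0.256) and the second was (adjusted p = 2.09e-05). Lower in dnHIF1a were the kinase gene pim3 (-2.11 ± 0.27, adjusted p = 0.000374), the haptoglobin gene hp (-2.03 ± 0.13, adjusted p = 1.96e-06), the matrix gene thbs4b (-1.88 ± 0.15, adjusted p = 1.39e-05) and ak1 (-2.06 ± 0.11), spint2 (-2.02 ± 0.23) and znf326 (-1.88 ± 0.20). The chemokine gene ccl27a was lower at 3.45 ± 0.049 against 6.44 ± 0.61 (SD, n = 3, adjusted p = 0.0206), here with the low level in dnHIF1a. It lost its call without dnHIF1a amputated array 1 (adjusted p = 0.0635) or 2 (0.065) or WT amputated array 3 (0.0777). The stress response gene ddit4 (-1.77 ± 0.42, adjusted p = 0.0162) lost its call without the same arrays (adjusted p = 0.0536, 0.0758 and 0.0663). Both calls were also lost with the erythrocyte covariate (adjusted p = 0.129 for ccl27a, and -1.72 with adjusted p = 0.112 for ddit4).

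Macrophage and pan-leukocyte markers were lower in amputated dnHIF1a hearts, 10 lower and 0 higher of 25 (22 and 0 adjusted over the list alone; median -0.51, adjusted p = 1.79e-09), for example ctss2.2 (-1.02 ± 0.13, adjusted p = 0.000412). Matrix genes (6 lower and 1 higher of 30, 9 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.000431) were lower. Matrix enzymes (10 lower and 0 higher of 17, 10 and 0 adjusted over the list alone; median -0.52, adjusted p = 6.05e-05) were lower too. Among the latter were mmp2 (-0.66) and mmp14b (-0.62). Also lower were erythrocyte markers (7 lower and 0 higher of 24, 8 and 0 adjusted over the list alone; median -0.66, adjusted p = 6.05e-05) and interferon genes (4 of 16 lower, 4 adjusted over the list alone; median -0.37, adjusted p = 0.00372). P53 and apoptosis genes were lower (3 of 16 lower, 3 adjusted over the list alone; median -0.26, adjusted p = 0.00333), with caspa (-0.82). Cardiomyocyte markers were higher (7 higher and 1 lower of 25, 7 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.00333), with ldb3a (0.61). So was oxidative phosphorylation (15 higher and 3 lower of 87, 18 and 3 adjusted over the list alone; median 0.093, adjusted p = 0.000827). None of these calls was made with an estimated correlation. It gave adjusted p = 0.319 with an estimated correlation for macrophages, 0.319 for matrix, 0.319 for matrix enzymes, 0.692 for erythrocytes, 0.533 for interferon, 0.319 for p53, 0.319 for cardiomyocytes and 0.738 for oxidative phosphorylation. The erythrocyte covariate ended the calls of erythrocytes (by construction, median 0.044, adjusted p = 0.778) and oxidative phosphorylation (0.051, adjusted p = 0.221), and moved the medians of interferon to -0.20 and of p53 to -0.17, both still called.

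Smaller shifts were called for ribosomal proteins (median 0.08, adjusted p = 0.00588, 2 of 79 higher and 1 lower) and the tricarboxylic acid cycle (median 0.12, adjusted p = 0.0387, 3 of 24 higher and 1 lower). Further ones were called for DNA replication (median -0.15, adjusted p = 0.00974, 1 of 47 lower), mitosis (median -0.16, adjusted p = 0.0205, 1 lower and 1 higher of 46) and epithelium (median -0.077, adjusted p = 0.0387, 4 of 33 lower). Adjusted over the list alone, 0 ribosomal, 5 tricarboxylic acid cycle, 0 replication and 1 mitosis genes were higher and 0, 1, 1 and 1 lower, with 4 epithelial genes lower. With an estimated correlation the adjusted p was 0.738 for ribosomal proteins, 0.738 for the tricarboxylic acid cycle, 0.738 for DNA replication, 0.738 for mitosis and 0.738 for epithelium. With the erythrocyte covariate it was 0.672 for the tricarboxylic acid cycle (median 0.042), 0.62 for DNA replication (-0.0065), 0.601 for mitosis (-0.038) and 0.357 for epithelium (-0.005). Each of these calls was lost without single arrays. Ribosomal proteins lost it without WT amputated array 2 (adjusted p = 0.107), and DNA replication without WT amputated array 3 (0.664, median 0.0067) or dnHIF1a amputated array 3 (0.107). Without WT amputated array 3 the p was 0.51 for mitosis, 0.341 for the tricarboxylic acid cycle and 0.513 for epithelium. Without dnHIF1a amputated array 2 it was 0.0782 for mitosis, 0.116 for the tricarboxylic acid cycle and 0.0501 for epithelium. Mitosis was also lost without dnHIF1a amputated array 3 (0.0711). The tricarboxylic acid cycle (0.0991) and epithelium (0.1) were lost without dnHIF1a amputated array 1, and epithelium without WT unamputated arrays 1 (0.0536) and 2 (0.0526). Medians moved by over 1.5 times without single arrays, for the tricarboxylic acid cycle to 0.076 (dnHIF1a amputated 2), 0.20 (dnHIF1a amputated 3) and 0.074 (WT amputated 3), for ribosomal proteins to 0.05 (WT amputated 2) and for mitosis to -0.032 (WT amputated 3). They did so for DNA replication, to -0.23 (WT amputated 2) and 0.0067 (WT amputated 3), and for epithelium, to -0.14 (WT amputated 2) and 0.025 (WT amputated 3). In all, 2000 probe sets (12.9%) were called, 954 higher and 1046 lower. With the erythrocyte list mean as a covariate 806 were called, 364 higher and 442 lower. The count was 1236 and 1138 without dnHIF1a amputated arrays 1 and 2 and 1279 without WT amputated array 1. Between unamputated and amputated hearts 750 probe sets shared a call, 710 of them with the same sign (361 higher and 349 lower, where independent lists would share 55.5 and 58.2). These lists too share the estimate of spread per probe set and are not independent.

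**Figure D3:**
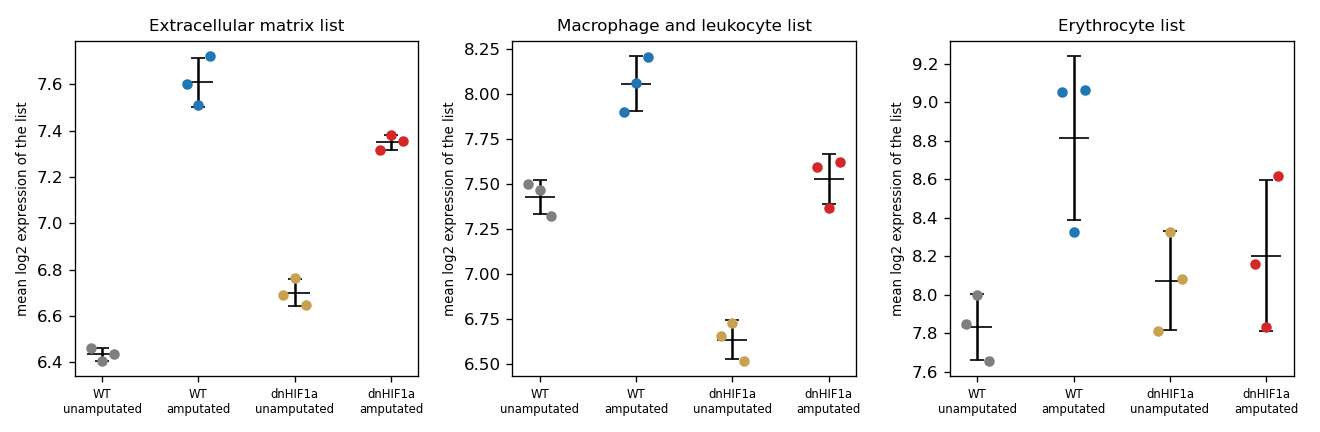
Mean log2 expression of the extracellular matrix, macrophage and pan-leukocyte, and erythrocyte lists on each array (points), by group, with the group mean and 1 SD (bars, n = 3). The matrix mean was 6.43 in unamputated and 7.61 in amputated WT hearts and 6.70 and 7.35 in dnHIF1a hearts, and the leukocyte mean was 7.43, 8.06, 6.64 and 7.53 in the same order.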

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

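The test of the difference between the responses of the genotypes was planned, while the tests of explanations, the splits of the arrays, the erythrocyte covariate and the genes hbaa1 and hbba2 were chosen only after the results were seen.

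The extracellular matrix list rose less in dnHIF1a than in WT hearts (median difference -0.45), and so did postnb (-2.60). A smaller share of wound tissue would shrink all its transcripts alike. On the linear scale the increment in dnHIF1a was divided by that in WT, gene by gene, for genes with a positive WT difference. The median ratio was 0.531 over 28 matrix genes (0.505 to 0.592 without single arrays). It was 0.988 over 23 macrophage and pan-leukocyte markers (0.868 to 1.29). Taking genes by their WT difference can shift these ratios. A smaller share of wound tissue stays open, since the macrophage and pan-leukocyte markers were lower in dnHIF1a in unamputated hearts (median -0.86, adjusted p = 0.255 with an estimated correlation). They were also lower in amputated hearts (median -0.51, adjusted p = 0.319 with an estimated correlation). Such a difference in their levels would leave their increments undecided. For the list mean, a higher starting level alone (unamputated difference 0.27) is argued against by the amputated arrays. There the mean was -0.26 in dnHIF1a minus WT, with a gap of 0.13 between the groups against a largest SD of 0.11. With an estimated correlation that lower amputated level was not called (adjusted p = 0.319). The starting level still makes up part of the difference. For postnb the unamputated arrays read 8.62 to 9.27 in dnHIF1a and 6.45 to 7.46 in WT. Its amputated arrays lay closer, at 10.54 to 10.91 and 11.25 to 11.71. With the erythrocyte covariate the list median moved from -0.45 to -0.33 and was still called at the preset correlation. This argues against blood content, as read by the erythrocyte list, as the whole cause at that setting. The covariate was not run with an estimated correlation. It also takes up change due to amputation, so how much of the difference follows blood is not shown. The gene postnb lost its call as its value shrank and its error grew (-2.60 ± 0.33 before and -2.24 ± 0.40 after). So did col1a2 (-1.36 ± 0.20 before and -1.11 ± 0.24 after). An effect of dnHIF1a on the matrix response remains a hypothesis, and the background of the transgenic line and any tamoxifen treatment stay open as untested.

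Erythrocyte markers were higher in amputated WT hearts (median 0.79; adjusted p = 0.475 with an estimated correlation) and the difference of the responses had a median of -0.80 in dnHIF1a minus WT (adjusted p = 0.481 with an estimated correlation), where 0 of 24 were called lower and 1 higher. The abundant haemoglobin genes hbaa1 (14.05 to 14.31 on unamputated and 14.81 to 15.04 on amputated arrays) and hbba2 (10.65 to 12.69 and 13.44 to 14.33) rose in WT, with hbaa1 at the array maximum on WT amputated arrays 1 and 3, so that no size is given. Retained blood is a candidate explanation. Within groups the 24 genes deviated together from array to array, with a mean pairwise correlation of 0.584, against 0.149 as the highest of 10000 random lists of that size. Markers of a single cell type would do so under any cause of varying red cell RNA, and no other marker list was compared. The correlation therefore does not favour retained blood over another cause. A change of red cell content of the heart that belongs to regeneration would give the same values and was not tested, and 1 of the 24 genes is in another list.

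The other differences between the responses of dnHIF1a and WT hearts are given as values. Differences were positive for odc1 (2.34), socs3b (2.18), cisha (1.67), psmb8a (1.60), pprc1 (1.45), psmb12 (1.35), ywhag2 (1.35) and phlda3 (1.28). They were negative for musk (-3.23), ccng2 (-2.26), arrdc2 (-2.11), ifi44f1 (-2.05), tppp3 (-1.99), zdhhc2 (-1.90) and nt5dc2 (-1.80). List medians were 0.42 for the heat shock response, 0.32 for macrophage and pan-leukocyte markers, 0.21 for glycolysis, 0.19 for cardiomyocyte markers, 0.13 for oxidative phosphorylation and -0.18 for epithelium. They were -0.23 for epicardium and fibroblast markers and -0.067 for matrix enzymes. The macrophage and pan-leukocyte list mean started lower in dnHIF1a (6.64 against 7.43 in WT) and stayed below WT after amputation (7.53 against 8.06). Without single arrays medians moved by over 1.5 times to -0.13 (dnHIF1a unamputated 1), -0.36 (WT unamputated 1), -0.11 (dnHIF1a amputated 3) and -0.14 (WT amputated 3) in epicardium and fibroblast, to -0.34 (WT unamputated 1), -0.01 (WT unamputated 3), -0.027 (dnHIF1a amputated 1), -0.12 (dnHIF1a amputated 2), -0.33 (WT amputated 2) and -0.005 (WT amputated 3) in matrix enzymes, to 0.12 (WT unamputated 1) and 0.12 (WT amputated 3) in glycolysis and to -0.018 (WT amputated 3) in epithelium. With an estimated correlation none of these 8 list calls was made, with adjusted p = 0.229 with an estimated correlation for epicardium and fibroblast and 0.482 for matrix enzymes. With the erythrocyte covariate the calls of glycolysis, cardiomyocyte, oxidative phosphorylation, epithelium and matrix enzymes were lost (adjusted p = 0.0544 to 0.135), and of the 15 genes named here psmb8a and psmb12 kept theirs. In most of the others the value stayed about as large while the error grew, as for odc1 (2.34 ± 0.38 before and 2.67 ± 0.48 after), whereas ifi44f1 (-2.05 ± 0.47 before and -0.86 ± 0.28 after) and nt5dc2 (-1.80 ± 0.33 before and -1.31 ± 0.38 after) came out smaller.

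Among 115 control probe sets, which the comparisons leave out, 2 unnamed in the platform table were called between unamputated genotypes with a difference of at least 1 log2 unit. They differed by 6.30 and 1.96 in dnHIF1a minus WT. Over the 6 arrays of each genotype the first read 12.77 to 13.41 in dnHIF1a and 5.99 to 6.97 in WT, and the second 7.10 to 8.90 and 4.87 to 5.52. The labels say that the line carries a GFP cassette, and what these probe sets match was not analysed here.

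For comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05. The real split called 3532 probe sets in WT (highest other 2), 1511 in dnHIF1a (highest other 0), 1764 between unamputated genotypes (highest other 1) and 2000 between amputated genotypes (highest other 0), so 1 split of each set reached the real value. For the difference of the responses, 2 of 100 splits of genotype within treatment, the real one included, called as many, with 347 for the real split and 350 as the highest other. All splits but the real one mix or exchange the lines, and mixing them adds the genotype difference to the spread within groups, which can lower their counts. This count therefore does not settle whether chance can be excluded. A split that exchanges the genotypes in a single treatment, which was not among those drawn, called 2883, since it carries the genotype difference into the response.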

How the results depend on the processing

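Of the alternatives, the erythrocyte covariate was chosen only after the data were seen. Counts of called probe sets stayed within 1.5 times those reported under repeated quantile normalization, median centring, leaving out the dimmest or the flattest part, the trended and robust prior, array weights and the replicate block. With the replicate block they were 3296 in WT, 1339 in dnHIF1a, 311 for the difference of the responses, 1666 between unamputated and 1789 between amputated genotypes, and arrays correlated best with their own number in 7 of 24 cases. The fold cutoff, which by construction removes small changes, left 374, 164, 120, 253 and 213 in the same order. Only the compared groups gave 2338 in WT. With the erythrocyte covariate, whose amputated and unamputated WT arrays do not overlap, 654 were called in WT, 24 for the difference of the responses and 806 between amputated genotypes. For the last 2 settings the cause was not tested.

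Of 30 lists, estimated correlation called 2 in WT, 5 in dnHIF1a, 1 for the difference of the responses, 0 between unamputated and 0 between amputated genotypes. Fry, which does not compare a list with other genes, called 4 for the difference and 8 between amputated genotypes. Without the dimmest part of the genes, where fewer genes were tested, 8 were called in WT and 8 between amputated genotypes, and with the erythrocyte covariate 5 for the difference and 7 between amputated genotypes. The skeletal muscle median in WT reversed to -0.082 with that covariate, and the cause was not tested.

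Leaving out each array in turn gave 2599 to 3449 probe sets in WT, 909 to 1774 in dnHIF1a, 149 to 590 for the difference, 1182 to 1754 between unamputated and 1138 to 2317 between amputated genotypes, 10 to 16, 9 to 11, 9 to 13, 7 to 8 and 9 to 13 lists in the same order, and a correlation of the responses of 0.528 to 0.618. Of 52 list calls 16 and of 375 calls of named genes 108 were lost without at least 1 array. The count was lowest without dnHIF1a amputated array 1 in dnHIF1a (909) and for the difference (149), and without array 2 of that group between amputated genotypes (1138). For the difference it was highest without WT unamputated array 3 (590). The highest-variance probe set and the mean of all probe sets ended 1 list call each, repeated quantile normalization 10 and the trended prior 25 gene calls. The replicate block ended 25 gene calls and no list call, and the erythrocyte covariate ended 126 gene and 16 list calls besides that of skeletal muscle in WT, which reversed. Among these, the calls of the erythrocyte list were lost by construction, since its mean is the covariate.

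Other probe sets of named genes ended 27 calls and reversed the sign in 14 cases, sign changes of uncalled genes not counted. These were in WT fn1a (-0.21), top2a (0.12) and mpx (0.17 and 0.033), in dnHIF1a fn1a (-0.13), and for the difference of the responses col5a2a (0.01). Between unamputated genotypes they were kif20a (-0.093), kif23 (0.013) and atp2a2a (-0.067), and between amputated genotypes kif23 (0.02), lama4 (-0.0033), col5a2a (0.16), fas (0.087) and adgrl4 (-0.11). The cause was not tested.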

Other observations

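All patterns, lists and tests in this part, and the genes cry2, nr1d2b, bmal1a and fkbp5, were chosen only after the results were seen.

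Clock genes differed between amputated and unamputated hearts of both genotypes, with ciarta (4.08 in WT, 2.83 in dnHIF1a), cry2 (1.66, 1.46) and nr1d2b (1.19, 1.06) higher and nfil3-5 (-3.66, -3.88) and bmal1a (-1.19, -0.93) lower. Not every gene followed this pattern. Unlike nfil3-5, nfil3-6 was higher after amputation in WT, at 8.18 to 9.45 on unamputated and 10.16 to 10.61 on amputated arrays. In dnHIF1a its arrays overlapped, at 8.93 to 9.77 and 9.24 to 9.4. The mean of 10 repressor and D-box genes minus that of 9 genes with ROR elements differed by 1.79 in WT and 1.63 in dnHIF1a, with a two-sided exact permutation p within genotypes of 0.005, the smallest that 400 relabellings can give, which restates the difference that prompted the test and adds no support. Collection at another phase of the day is a candidate explanation that cannot be told apart from an effect of amputation, because the labels give no time of collection and every amputated array would share it. A change in cell makeup stays open too, as the lowest marker list median in WT was -0.13 and the ROR-element genes, with a median of -0.19 and an SD of 1.41, lay mostly below 0 (1 of 9 above it in WT and 0 in dnHIF1a) but spread too widely to be parted from that list.

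Of 20 glucocorticoid and FOXO target genes, 12 were higher and 0 lower in amputated WT hearts (median 1.00), and 0 higher and 4 lower in amputated dnHIF1a hearts (median -0.21). The difference of the responses had a median of -1.42 with 7 lower and 0 higher. In dnHIF1a minus WT the median was 0.70 in unamputated hearts (12 higher, 1 lower) and -0.48 in amputated hearts (0 higher, 8 lower). Within the unamputated dnHIF1a group fkbp5 read 11.08, 11.63 and 7.27. Several other members, among them klf9, cited4a and tsc22d3, were also lower on array 3 of that group, while others, such as irs2a and trim63a, were higher there. The medians involving that group thus depend in part on single arrays. Each response and the comparison of unamputated genotypes share unamputated arrays.

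Of 11 class I antigen processing genes, 8 were lower and 1, mhc1ufa, higher in unamputated dnHIF1a than in unamputated WT hearts (median -0.53). In the WT response 6 were lower and 0 higher, and both comparisons share the 3 unamputated WT arrays. The group means of psmb8a were 9.87 in unamputated and 8.76 in amputated WT hearts and 7.86 and 8.35 in dnHIF1a hearts. Of the 11 genes, 6 (b2m, psmb8a, psmb9a, psmb13a, psme1 and psme2) also sit in the interferon response list. These values are therefore not separate from the result of that list.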
